A study of Mus musculus with 6 samples.

How the data were processed

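Total RNA was extracted with Trizol from sorted T cells, and biotin-labelled cRNA was made from 2 µg and hybridised to Affymetrix arrays, per the labels' protocols. The authors deposited 1 table with 1 intensity per probe set and array, for 45101 probe sets and 6 arrays. The submitters' processing notes name Partek and MAS5, with no versions. The deposited intensity values are linear, and the mean of each array, after the highest and lowest 2% were trimmed, was 500.003, which is the scaling that MAS5 applies. Background correction and summary of probes were done before deposit. How faint signals were treated is not given in the sources used here, and MAS5 leaves such values noisy, so the log2 scale and the filter on dim probe sets affect the counts. All per-sample columns were used.

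Groups were taken from sample titles, with 3 wild type and 3 CTLA-4 KO arrays. The titles call them biological replicates, but separate animals are not stated. Donor sex shows at least 2 donors in each group, and p-values measure only the spread between these samples, part of which may be technical. Replicate numbers are shared by the genotypes. Deviations from the group means correlated at 0.371, 0.24 and 0.254 for arrays 1, 2 and 3 of both genotypes, each over 0.1, so the numbers were taken to pair the arrays. The pairing comes from the numbers in the titles together with this check, and each pair also shared its donor sex, read from Xist and Y-linked genes.

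Values were turned into log2(intensity + 16), and 64 AFFX control probe sets were left out. Probe sets were kept where their mean over all 6 arrays reached the 40th percentile, a floor of 35.4 in intensity, which left 27022. Pearson's r between arrays over these probe sets, which are not independent replicates, lay between 0.968 and 0.983. A linear model per probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, 4 residual degrees of freedom), with p-values counted in both directions and adjusted by Benjamini-Hochberg over all kept probe sets, at a threshold of 0.05. The main model had no block. All log2 differences are CTLA-4 KO minus wild type on this scale, which understates changes of dim genes. Intensities in the text are means ± SD of the 3 arrays before the log.

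Gene names came from an annotation table of the array. It gave 1 gene for 34958 probe sets, several for 932, which were not named, and none for 9211. Symbols were updated through gene IDs, which matched the RefSeq table of GRCm38.p6 for 34754 probe sets. As the array files name no build, this table was used for names, chromosomes and gene order, and no coordinates are given. Each gene was represented by the probe set with the highest mean over all arrays, which gave 11990 genes.

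In all, 32 gene lists with 549 genes were fixed, of which 444 were measured, and a gene can be in several lists. The 28 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation beside it. By the preset test 14 lists passed, and with an estimated correlation none did, where a p of 0.0537 was the lowest after adjustment. The test fry, which asks whether genes of a list move one way and does not compare them with other genes, passed 15 lists. Neighbours of Ctla4 were tested with Fisher's exact test. The targeted gene also had an exact permutation test of the group means.

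The genes named were Ctla4 and, in each direction, the 12 with the largest log2 difference among genes past the threshold whose values did not overlap between genotypes, clone and predicted gene names passed over. From each list, up to 4 members with the smallest p were taken, and all of the sex-linked and CD8 lists. Ctla4 counts among the 12 lower genes. Batf, Il17a, Bcl6, Icos, Ifng, Foxp3, Il2ra and Ikzf2 fall outside this rule and were chosen after their values were seen. The groups, lists, tests, naming rule and most alternatives were chosen before the data were examined. Those alternatives were the dimness filter, the pseudocount, normalization between arrays, the kind of moderation, array weights, the replicate block, thresholds, cross-hybridising probe sets, the size of the neighbourhood and leaving out each array. A term for donor sex, the male arrays alone and terms for the Gapdh and the Actb 5' to 3' ratio were added after seeing the data.

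The fit was tested on simulated data for the same comparison with 27022 probe sets, of which 100 were changed 2-fold and 100 were changed 4-fold. Without a block, 50% of the 2-fold and 88% of the 4-fold changes were called, and 0.719% of calls were false. With the replicate block 30% and 84% were called and 2.56% of calls were false. The simulated noise was independent between probe sets, with a replicate effect of the same relative size in each, and the rates hold for that setting. The block lowered the calls from 139 to 117 there, but raised them from 339 to 2341 in the real arrays. These rates therefore do not describe the block fit of the real arrays. Figures were drawn with matplotlib 3.10.9.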

Results

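Gene expression was measured on Affymetrix arrays in 5C.C7 T cells, which carry a transgenic receptor for a peptide of moth cytochrome c (MCC). Donor cells lacked RAG2 and were either wild type or knocked out for CTLA-4 (CTLA-4 KO), an inhibitory receptor of activated T cells that binds CD80 and CD86. They were transferred into B10.A mice, which were then immunized with the MCC peptide together with LPS, and the transferred cells were sorted on day 4. Each genotype had 3 arrays, made from 2 µg of total RNA each. All arrays had the same trimmed mean intensity, 500.003, and median intensities of 67.98, 69.47 and 75.23 in wild type and 62.08, 63.69 and 71.51 in CTLA-4 KO. The ratio of 5' to 3' Gapdh signal, a sign of RNA integrity, spanned 0.0955 to 0.25 in wild type and 0.109 to 0.205 in CTLA-4 KO. The same ratio for Actb averaged 0.471 ± 0.0982 in wild type and 0.601 ± 0.0791 in CTLA-4 KO (SD, exact permutation test with both directions counted, p = 0.3, n = 3 arrays), and the Actb 5' control probe set was 0.35 higher on the log2 scale (limma adjusted p = 0.653 over the control probe sets). Replicate 2 of each genotype had high Xist, at 14610 and 12600, and the other arrays had at most 106.7, with the Y-linked Eif2s3y the other way round, so the donors of replicate 2 appear female and the others male. The number of arrays limits the precision of every value.

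The design asks how the expression profile of the transferred cells differs between genotypes 4 days after immunization. Ctla4 itself fell from an intensity of 4900 ± 385 in wild type to 795 ± 14.4 in CTLA-4 KO (mean ± SD, n = 3 arrays), which was 16.2% of the wild-type level. The log2 difference was −2.60 ± 0.10 (SE, limma adjusted p = 1.45e-06). All CTLA-4 KO arrays lay below all wild-type arrays, and the exact permutation test, with both directions counted, gave p = 0.1, the smallest that its 20 arrangements allow. One probe set reads this gene, and its place relative to the deleted part is not known here. The fall in all 3 CTLA-4 KO arrays goes with the labels, but whether this probe set reads the deletion itself cannot be told. Without variance moderation the adjusted p of Ctla4 was 0.0538, and under the other alternatives it lay between 1.33e-08 and 0.00124.

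Among the genes that rose in CTLA-4 KO cells, Ap1s3, which encodes a small subunit of an adaptor complex of vesicle coats, led with 200 ± 16.1 in wild type and 4350 ± 687 in CTLA-4 KO, a log2 difference of 4.33 ± 0.14. Gzmb, the cytotoxic protease granzyme B, rose from 29.1 ± 31.4 to 330 ± 184. Il1r1, the signalling receptor for interleukin-1, rose from 99.3 ± 67.8 to 452 ± 21.1, and Lgals3, the lectin galectin-3, from 214 ± 18.6 to 1120 ± 398. Among the genes that fell, Lad1, which encodes the filament protein ladinin, went from 487 ± 145 to 60.9 ± 14.8, and Gpr83, a receptor enriched in regulatory T cells, from 809 ± 231 to 248 ± 16.9. Bach2, a transcriptional repressor that restrains effector differentiation, fell from 3070 ± 655 to 1350 ± 210.

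In all, 339 of 27022 tested probe sets changed at an adjusted p of 0.05, of which 212 were higher and 127 lower in CTLA-4 KO cells. They named 203 of 11990 tested genes, 143 higher and 60 lower, and in each of these the values of the genotypes did not overlap. Over all tested probe sets, 21% had no overlap, where chance gives 10%. At least a 2-fold difference was seen for 142 of the 339. With replicate number as a block, which compares the arrays of each pair, 2341 probe sets changed (1044 higher and 1297 lower), among them all 339. The share of higher calls was 62.5% here and 81.5% when each array was centred on its median, which called 303 probe sets. With the Actb 5' to 3' ratio as a term, which was added after seeing the data, 22 probe sets changed (9 higher and 13 lower), 21 of them among the 339, against 376 with the Gapdh ratio as a term.

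The largest increases included several genes better known from other cell lineages. Dnase1l3, a secreted endonuclease, rose from 4.93 ± 3.92, a level near background, to 140 ± 58.3 (adjusted p = 0.00577). Cebpa, a transcription factor of myeloid cells, rose by 2.12 ± 0.24 on the log2 scale (adjusted p = 0.00415), and Cd22, a sialic acid-binding receptor of B cells, by 1.97 ± 0.19 (adjusted p = 0.00193), to 887 ± 179 from 214 ± 42.5. The markers of B cells and of myeloid cells did not shift with them as lists, as given further on. Log2 differences were 2.25 for Lgals3 (adjusted p = 0.00193), 2.19 for Il1r1 (0.0173), 2.05 for the zinc finger gene Plagl1 (0.0127) and 2.02 for the channel gene Cnga1 (0.0432). The motor protein gene Myo1f rose by 1.98 (0.00193). Gzmb (adjusted p = 0.0288), the orphan receptor gene Gpr25 (0.0162) and Ryr1, a calcium release channel (0.015), also rose. Gzmb, Dnase1l3, Gpr25 and Ryr1 had wild-type means under the filter floor of 35.4, near background, so the size of their rise and their place among the largest are not reliable.

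The genes that fell furthest after Lad1 (log2 difference −2.68, adjusted p = 0.00193) and Ctla4 were Gpr83 (−1.61, 0.00537) and Ms4a4c, which went from 4830 ± 917 to 1600 ± 347 (−1.59, 0.00294). Chn2, an activator of Rac GTP hydrolysis, fell by 1.39 (adjusted p = 0.0103), the alcohol dehydrogenase gene Adh1 by 1.28 (0.0215), Bach2 by 1.17 (0.0112) and Abca1, a cholesterol exporter, by 1.15 (0.0231). Lancl1 fell by 1.15 (0.00991), but its other probe set had a difference of 0.33. St8sia6, a sialyltransferase, fell by 1.14 (0.00443), the kinase gene Dstyk by 1.13 (0.0402) and the ubiquitin ligase gene Hectd2 by 1.11 (0.00223). Of the 24 genes named so far, 14 were called whichever array was left out, and Cnga1 and Dstyk were called in 1 of 6 such fits, Gzmb and Adh1 in 2 and Abca1 in 3. With the Actb ratio as a term, 6 of the 24 were called, namely Ctla4, Ap1s3, Gpr83, Ms4a4c, Chn2 and Hectd2. The log2 differences of the other 18 kept their direction and were 67.9% to 131% of those without the term (median 96.7%), while their SE had a median of 1.36 times that without it. The count of 339 became 217, 171 and 92 without wild type replicates 1, 2 and 3, 204, 62 and 203 without CTLA-4 KO replicates 1, 2 and 3, 20 without the intensity trend, and 0 in limma fits without moderation, where 3611 probe sets had an unadjusted p under 0.05 against 4216 with it.

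**Figure D1:**
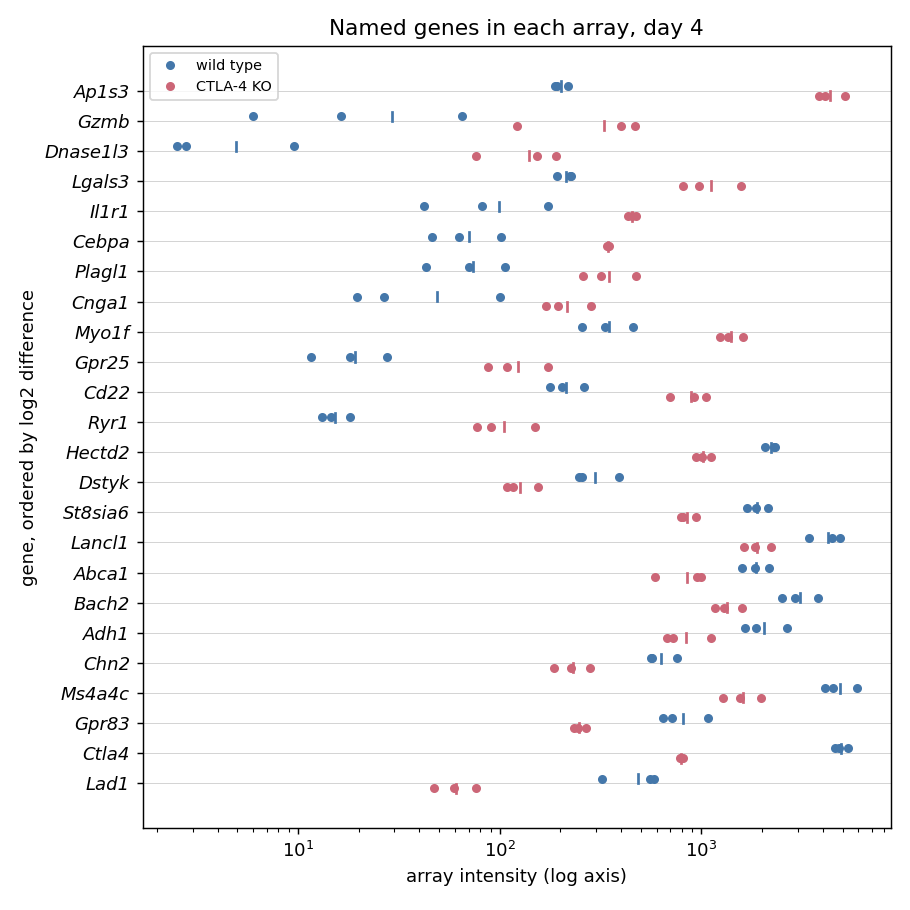
Intensity (log axis) of the 24 named genes in each of the 6 arrays, with wild type and CTLA-4 KO as separate points and a vertical tick at each genotype's mean of 3. The naming rule took only genes whose points do not overlap between genotypes, and they run from Ap1s3 (200 against 4350) at the top to Lad1 (487 against 60.9) at the bottom.

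Genes grouped by function, in lists fixed in advance, were compared next. Genes of mitosis were higher as a group in CTLA-4 KO cells by the preset test (camera adjusted p = 3.37e-28, adjusted p = 0.167 with an estimated correlation): 17 of 33 measured members rose and none fell, with a median log2 difference of 0.93. Mki67, the proliferation marker Ki-67, rose from 3160 ± 290 to 7010 ± 1470, and Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, from 270 ± 32.7 to 833 ± 226. Cdc20, an activator of the anaphase-promoting complex, rose from 1890 ± 208 to 4010 ± 907, and Hmmr from 295 ± 28.5 to 718 ± 150. DNA replication genes had a median of 0.49 (camera adjusted p = 1.73e-12, adjusted p = 0.192 with an estimated correlation), and 4 of 27 rose: Rrm2, a subunit of ribonucleotide reductase (1730 ± 167 to 4070 ± 1020), Lig1, Uhrf1 and Mcm5. Adjusted over the list alone, 32 mitosis genes and 17 replication genes rose, and none fell. The mitosis median was 0.89, 1.26 and 0.67 in replicate pairs 1, 2 and 3, and pair 2 was the female one. In these pairs the Actb 5' to 3' ratio was 0.418, 0.41 and 0.584 in wild type and 0.567, 0.691 and 0.544 in CTLA-4 KO, and with that ratio as a term the mitosis median was 0.86 and the replication median 0.41.

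Genes of biosynthesis and energy metabolism were also higher as groups by the preset test, and none of these lists passed with an estimated correlation, where adjusted p = 0.0537 was the lowest. The Actb 5' to 3' ratio averaged 0.471 in wild type and 0.601 in CTLA-4 KO, and all 5 lists below passed with it as a term. Cholesterol synthesis genes had a median of 0.48, and 2 of 16 rose, the isomerase gene Idi1 (643 ± 104 to 1210 ± 126) and the epoxidase gene Sqle (630 ± 31.5 to 1090 ± 136). Adjusted over the list alone it was 9 (camera adjusted p = 3.29e-08, adjusted p = 0.149 with an estimated correlation). Glycolysis genes had a median of 0.39 and 1 of 15 rose, the isomerase gene Tpi1 (1930 ± 137 to 2880 ± 226), with 9 adjusted over the list alone (4.62e-07, adjusted p = 0.0869 with an estimated correlation). Ribosome biogenesis genes had a median of 0.34 and all 23 had positive differences. Of these, Nolc1, a nucleolar chaperone, rose from 992 ± 54.6 to 1520 ± 147, and 14 rose adjusted over the list alone (4.92e-10, adjusted p = 0.0537 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.22 and 1 of 30 rose, the ATP synthase gene Atp5o, with 2 adjusted over the list alone (5.96e-08, adjusted p = 0.153 with an estimated correlation). Unfolded protein response genes had a median of 0.19, with 1 of 17 higher and 4 adjusted over the list alone (0.00287, adjusted p = 0.149 with an estimated correlation). The one that rose, Asns (205 ± 9.97 to 446 ± 72), encodes asparagine synthetase and is a target of the amino acid response as well.

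Among lists of helper T cell programmes, 5 of 8 measured genes of the Th17 list rose, with a median of 0.68 (camera adjusted p = 2.81e-07, adjusted p = 0.0695 with an estimated correlation) and 5 adjusted over the list alone. They were Il1r1, Rora (963 ± 33.6 to 1600 ± 61.9), Ahr (728 ± 109 to 1310 ± 82.9), Batf (1300 ± 178 to 2030 ± 82.1) and Il21 (2220 ± 378 to 3870 ± 94.2). Batf and Il21 also act in follicular helper cells. The cytokine gene Il17a itself was dim in both genotypes, at 41.9 in wild type and 64.7 in CTLA-4 KO (adjusted p = 0.741), and the other probe set of Ahr had a difference of −0.70. Of 17 follicular helper genes 4 rose, with a list median of 0.28: Cxcr5, the receptor that guides cells to B cell follicles (3490 ± 659 to 7560 ± 1280), Tox2 (6140 ± 1220 to 11800 ± 1040), Pou2af1 (1940 ± 197 to 3700 ± 469) and Il21. Adjusted over the list alone, 9 were higher and 3 lower (0.00682, adjusted p = 0.149 with an estimated correlation), and the median was 0.49 with the Actb ratio as a term. Bcl6, the lineage factor, had 2260 ± 186 and 3120 ± 146 (adjusted p = 0.0609, and 0.0112 with the replicate block), while Icos had 17000 and 17300. Of 14 Th1 genes Cxcr3, a chemokine receptor, rose from 5360 ± 1650 to 10400 ± 1040, with 3 adjusted over the list alone and a median of 0.22 (0.0359, adjusted p = 0.167 with an estimated correlation). Il18rap had 618 ± 65.4 and 937 ± 47.1 (limma adjusted p = 0.0581, and 0.00669 with the replicate block). Il12rb1 had 319 ± 58.5 and 534 ± 54.3 (0.0709 and 0.00588), and Tbx21 had 223 ± 70.5 and 340 ± 49.9 (0.246 and 0.0331). Of the 14 genes, 9 had positive differences. Ifng had 188 and 195. The Th1 list no longer passed under median centring (adjusted p = 0.0655), without the intensity trend (0.0595), in male arrays (0.0656), with the Gapdh (0.067) or Actb (0.234) ratio as a term, or without wild type replicate 1 (0.0565) or CTLA-4 KO replicate 2 (0.0788). Its median lay between 0.17 and 0.31 in these fits, with 0.22 with the Actb term as without it, and was 0.12 with no dimness filter, where the list passed.

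Lists that were lower in CTLA-4 KO cells by the preset test, and did not pass with an estimated correlation, held genes of regulatory, naive and anergic T cells and interferon-stimulated genes. Of 15 regulatory T cell genes 3 fell: Gpr83, Nrp1, the co-receptor neuropilin-1 (9070 ± 190 to 6060 ± 334), and Izumo1r, the folate receptor FR4 (6290 ± 668 to 3810 ± 298). The median was −0.28, with 4 lower adjusted over the list alone (camera adjusted p = 0.00287, adjusted p = 0.149 with an estimated correlation), and without wild type replicates 1 and 2 and CTLA-4 KO replicate 3 the median was −0.16, −0.18 and −0.13. Ikzf4 had 525 ± 125 and 297 ± 52.6 (limma adjusted p = 0.102, and 0.00522 with the replicate block), and 4 of the 15 genes had positive differences. Foxp3 of this list was dim in both genotypes, at 70 ± 35.5 and 47.9 ± 4.81 (limma adjusted p = 0.622). Il2ra was dim as well, at 60.8 and 71.5 (0.827), and the bright Ikzf2 had 10800 and 11200 (0.803). Of 16 naive and memory T cell genes Bach2 and Il7r, the interleukin-7 receptor (2990 ± 965 to 1430 ± 84.6), fell, with a median of −0.13 and 5 lower adjusted over the list alone (0.00827, adjusted p = 0.276 with an estimated correlation). That median was −0.22 and −0.062 without wild type replicates 1 and 2, −0.087 in male arrays, −0.045 under median centring and −0.25 with the mean of a gene's probe sets. Of 23 interferon-stimulated genes Ifih1, the RNA sensor MDA5, fell from 5940 ± 685 to 3930 ± 513, with a median of −0.18 and 4 lower adjusted over the list alone (0.000679, adjusted p = 0.251 with an estimated correlation), and the list did not pass with the Actb ratio as a term (median −0.12, adjusted p = 0.0641), while its median was −0.091 under median centring. Of 17 anergy-associated genes Izumo1r fell, with a median of −0.062 that turned to 0.026 under median centring and 2 lower adjusted over the list alone (0.0359, adjusted p = 0.167 with an estimated correlation). Cblb, a ubiquitin ligase that limits T cell activation, had 4760 ± 684 and 3060 ± 437 (adjusted p = 0.055, and 0.00136 with the replicate block). Neither the naive and memory list nor the anergy list passed in male arrays (adjusted p = 0.0544 for each) or without wild type replicate 2 (0.0639 for each). The anergy list also did not pass with no dimness filter (adjusted p = 0.051), under median centring (0.0673), without the intensity trend (0.105), with the Actb ratio as a term (0.105) or with the mean of a gene's probe sets (0.113). Its median was −0.14 with the Actb term, −0.10 with the Gapdh term, −0.13 in male arrays and after quantile normalization, −0.098 with array weights, −0.12, −0.098 and −0.027 without wild type replicates 1, 2 and 3, −0.024, −0.099 and −0.11 without CTLA-4 KO replicates 1, 2 and 3, and −0.062 under the dimness, trend and probe set alternatives.

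With the replicate block the same 14 lists passed, 10 up and 4 down, and none passed there with an estimated correlation. The block raised the number of changed members to 31 for mitosis, 14 for replication, 9 for glycolysis, 8 each for cholesterol synthesis and follicular helper genes, with 3 follicular helper genes lower, 7 for ribosome biogenesis, 5 for the unfolded protein response and 4 each for oxidative phosphorylation and Th1. Lower members rose in number to 6 for the naive and memory list, where 1 was higher, 5 each for the regulatory and interferon lists and 4 for anergy. Of the 53 genes other than Ctla4 that passed and were named by the fixed rule, 18 were called whichever array was left out. Without CTLA-4 KO replicate 2 the calls left were 21, without wild type replicate 3 they were 23, without wild type replicate 2 they were 32, and without CTLA-4 KO replicate 3, 1 and wild type replicate 1 they were 36, 40 and 43.

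**Figure D2:**
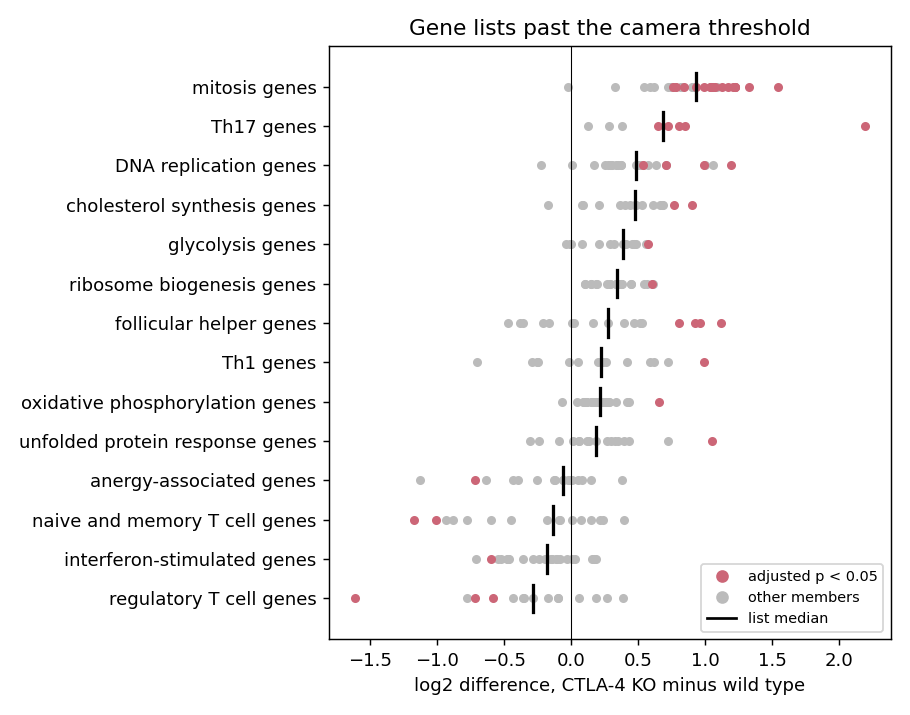
Log2 difference (CTLA-4 KO minus wild type, horizontal axis) of every measured member of the 14 lists that passed the camera test, with 1 list per line, coloured points for members past an adjusted p of 0.05 and a black tick at the list median. The mitosis median stands at 0.93 and the regulatory T cell median at −0.28, and several lists with few coloured points have most members on one side of 0.

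The other 14 lists tested did not pass. Within them Cd96, an inhibitory receptor, fell from 3780 ± 324 to 2110 ± 162 (adjusted p = 0.00923) and was the 1 changed gene of 13 coinhibitory genes (list adjusted p = 0.102), with 2 higher and 2 lower adjusted over the list alone. Pdcd1, which encodes PD-1, had 4750 ± 696 and 6200 ± 129 (adjusted p = 0.122, and 0.0212 with the replicate block). Among 17 cytotoxic genes Gzmb rose and Id2, a transcriptional regulator, fell from 5820 ± 1330 to 2760 ± 418 (0.551), with 3 higher and 2 lower adjusted over the list alone. Fos rose from 630 ± 94.7 to 1120 ± 50.6 among 20 immediate early genes (0.261), with 4 adjusted over the list alone. Bcl2l11, the apoptosis inducer BIM, fell from 9110 ± 2220 to 4470 ± 365 among 20 apoptosis regulators (0.641), with 2 higher and 3 lower adjusted over the list alone. Il21 was the changed gene of 14 secreted cytokines (0.159), where Il2 had 347 ± 73.7 and 219 ± 27.7 (adjusted p = 0.151, and 0.0319 with the replicate block), and 2 were higher and 2 lower adjusted over the list alone. Cxcr5 and Cxcr3 were the changed genes of 21 homing receptors (0.0526), with 5 higher and 2 lower adjusted over the list alone, and the chaperonin gene Hspd1 (3620 ± 53.5 to 4920 ± 165) that of 10 heat shock genes (0.0715), with 2 higher adjusted over the list alone. With the replicate block the changed members numbered 1 higher and 2 lower for coinhibitory genes, 3 and 2 for cytotoxic genes, 4 and 1 for immediate early genes, 3 and 4 for apoptosis regulators, 2 and 2 for cytokines, 4 and 2 for homing receptors, and 2 higher for heat shock genes.

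No member passed among 16 costimulatory genes (list adjusted p = 0.882), 7 Th2 genes (0.855) and 25 TCR signalling components (0.882). Adjusted over the list alone these had 1 higher and 1 lower, 1 higher, and 2 higher and 2 lower. With the replicate block 2 costimulatory genes were higher, among them Cd27 (2140 ± 35.5 and 2960 ± 281, adjusted p = 0.00964). With it 3 were lower, among them Tnfrsf9 (1300 ± 202 and 962 ± 97.6, 0.0224) and Cd28 (12000 ± 525 and 9470 ± 232, 0.0299). With the block the Th2 genes Il17rb (921 ± 278 and 579 ± 200, 0.00406) and Gata3 (1640 ± 231 and 1250 ± 264, 0.0252) were lower and none passed as higher. The Th2 genes Ccr4 (74.9 ± 8.18 and 132 ± 4.45, 0.0623) and Il4 (92.1 ± 32.9 and 160 ± 45, 0.0567) had higher values without overlap and did not pass with the block. Of the TCR signalling components 2 were higher and 3 lower with it. Markers of other cell types were compared in the same way. Cd22 was the 1 changed gene of 8 B cell markers (0.95), where Bank1 was lower adjusted over the list alone, and Cd79b had 110 ± 8.79 and 91.5 ± 15.6. None passed of 12 myeloid and dendritic cell markers (0.368), 6 MHC class II genes (0.735), where 1 was lower adjusted over the list alone, or 5 stromal and endothelial markers (0.403), where 1 was higher and 1 lower adjusted over the list alone. The block gave 1 higher and 1 lower among B cell markers and among stromal markers, 1 lower among MHC class II genes and none among myeloid markers. Lyz2 of macrophages had 57.8 ± 27 and 30.2 ± 27.1, and Cd74 of antigen-presenting cells 199 ± 50 and 231 ± 25.5. For the Th2 and B cell lists the median was negative (−0.14 and −0.20) and the mean positive (0.0039 and 0.036), with both tests pointing down. For TCR signalling the median and mean were positive (0.013 and 0.0032) and for MHC class II the median was positive (0.035) and the mean negative (−0.020), again with both tests pointing down. Lists with under 5 measured members were not tested: Cd8a had 125 and 148, Cd8b1 211 and 242, the natural killer list held Gzma at 71 and 64.4, the erythroid and platelet list Epor at 93.3 and 63.5 and Itga2b at 139 and 117, and none of the 4 measured sex-linked genes passed.

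Genes that flank Ctla4 on chromosome 1 were compared with all other genes, because an allele moved between mouse strains carries flanking DNA with it. Of the measured neighbours, Acadl, a mitochondrial acyl-CoA dehydrogenase, fell from 2280 ± 162 to 1220 ± 202 (log2 difference −0.90 ± 0.13, adjusted p = 0.0136), and Bmpr2, a receptor for bone morphogenetic proteins, fell from 1290 ± 86.7 to 791 ± 49.4 (−0.70 ± 0.12, 0.0231). Sgo2a, a protector of centromeric cohesion, rose from 182 ± 11.8 to 321 ± 19.6 (0.76 ± 0.16, an adjusted p that rounds to 0.05 from below). These 3 were named after their values were seen, and 1 probe set stands for each gene here. Of the 5 other probe sets of the neighbour Kansl1l, 2 passed, and the 5 had log2 differences from −1.42 to 1.42. Of the 2 other probe sets of the neighbour Raph1, 1 passed, and their differences were −0.99 and −0.58. Kansl1l and Raph1 were also named after their values were seen. Among the 100 annotated genes on each side, 53 were measured and 11 of them (20.8%) had an unadjusted p under 0.01, against 847 of 11936 other genes (7.1%). Of the 11, 5 were higher and 6 lower. The lower ones included the costimulatory gene Cd28, 7 places from Ctla4 (log2 difference −0.34 ± 0.08, limma adjusted p = 0.0731). The odds ratio was 3.43 (Fisher's exact test, p = 0.00112). With 50 genes on each side it was 4.35 and with 200 it was 2.84. Under median centring the odds ratio was 2.35 and the test no longer passed (Fisher's exact test, p = 0.0519), and with the Actb ratio as a term it was 2.2 (Fisher's exact test, p = 0.123).

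**Figure D3:**
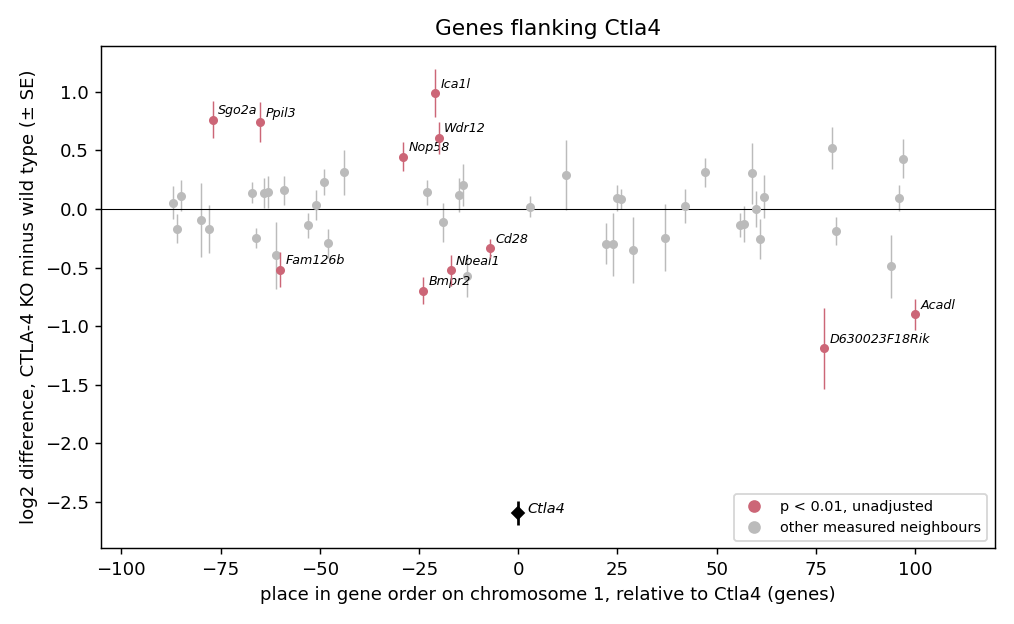
Log2 difference (CTLA-4 KO minus wild type, vertical axis, bars are SE) of Ctla4 (diamond) and its 53 measured neighbours by their place in gene order on chromosome 1 (horizontal axis), with coloured points for those with an unadjusted p under 0.01. The 11 coloured genes lie on both sides of 0, from Ica1l at 0.99 down to D630023F18Rik at −1.19, and none comes near Ctla4 at −2.60.

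By chromosome, 21 of 672 measured genes on chromosome 1 changed (3.12%), against 1.59% of genes elsewhere (Fisher's exact test, p = 0.00517). Adjusted over 20 chromosomes the p was 0.103, so this did not pass. Ap1s3, Lad1, Lancl1, Il1r1, Gpr25 and Dstyk also lie on chromosome 1, outside the 100 neighbours on each side. That limit was chosen in advance and does not mark where flanking DNA ends.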

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

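The comparison of donor sexes, the look at dim probe sets and the tests of RNA quality (by Gapdh and by Actb), donor sex and scaling were all chosen after the results were seen.

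An interaction term of genotype and donor sex passed for 4 lists with the preset correlation and for 0 with an estimated one, so no difference between the 1 female pair and the 2 male pairs was shown. The median difference of mitosis genes was 1.26 in the female pair and 0.78 in the male pairs, a gap of 0.47 (camera adjusted p = 7.8e-10). For DNA replication genes it was 0.62 and 0.36, a gap of 0.25 (0.000439). For TCR signalling components it was −0.13 and 0.11, a gap of −0.24 (0.00476), and for oxidative phosphorylation genes 0.13 and 0.23, a gap of −0.097 (0.0266). With an estimated correlation each had an adjusted p of 0.98, and the preset test has 1 female array per genotype behind it. No single probe set had an interaction at an adjusted p of 0.05 by limma, and 601 had an unadjusted p under 0.05, where chance gives 1351. The female pair is 1 pair, so its sex and anything else particular to that pair were not separated.

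Outside the probe sets kept for testing, 3 dim ones were higher in CTLA-4 KO when all probe sets were fitted. A second probe set of Uhrf1 had 4.94 in wild type and 72 in CTLA-4 KO (log2 difference 2.03, adjusted p = 0.0419). Aknad1 had 6.41 and 53.1 (1.62, 0.0489), and Kif5c had 2.23 and 25.1 (1.17, 0.049). The wild-type values are at background, and both means of Kif5c lie under the floor of 35.4, so the sizes are not reliable.

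The higher level of mitosis genes in CTLA-4 KO cells was set against RNA quality, array scaling and donor sex. The median was 0.93 without a term and 0.98 with the Gapdh 5' to 3' ratio as a term, where the SE of the difference in the list's mean was 0.252. The Gapdh ratio averaged 0.15 ± 0.0875 in wild type and 0.164 ± 0.0494 in CTLA-4 KO (SD), so its term could hardly move the difference. Means this close argue against RNA quality as read by Gapdh as the whole cause, within the wide spread of so few arrays. With the Actb ratio, which was higher in CTLA-4 KO in pairs 1 and 2, the median was 0.859, and the SE of the difference in the list's mean was 0.348. With so few arrays an SE of this size leaves room for no difference. The Actb fit therefore cannot decide, and RNA quality as read by Actb stays open as a part or the whole of the cause. After quantile normalization the median less that of all probe sets was 0.945, which argues against array scaling. Each genotype had 1 female and 2 male arrays, so a plain sex difference cancels. Whether the female pair carried much of the difference stays open. The median in male arrays was 0.782, where the SE of the difference in the list's mean was 0.333. An effect of the CTLA-4 genotype on the share of cells in division on day 4 may lie behind it, as a hypothesis found on the same arrays, and the timing of the sort and the number of transferred cells were not tested.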

How the results depend on the processing

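The sex term, the male arrays alone and the Gapdh and Actb terms were chosen after the results were seen, and the rest were planned. No result changed its tested direction under any alternative run. Counts of changed probe sets, genes higher and genes lower (339, 143 and 60) moved most. They were 111, 44 and 22 with no dimness filter, 20, 8 and 2 without the intensity trend, 0, 0 and 0 without moderation by limma (3611 probe sets with an unadjusted p under 0.05), 521, 218 and 89 with array weights, 46, 18 and 11 in male arrays, 22, 4 and 7 with the Actb 5' to 3' ratio as a term, 832, 309 and 165 at an adjusted p of 0.1, and 142, 66 and 24 with a 2-fold minimum. Genes lower were 99 with the 60th percentile filter and 28 under median centring. The cause was not tested, except that the 18 named genes that lost their call with the Actb term kept a median of 96.7% of their difference with an SE 1.36 times as large, that male arrays are fewer and that thresholds set their own counts.

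With the replicate block the counts were 2341, 657 and 413, and apart from genes that passed only there the block changed no other call. Leaving out 1 array gave 62 to 217 changed probe sets, 23 to 108 genes higher and 16 to 38 genes lower, lowest without CTLA-4 KO replicate 2, which gave 62, while wild type replicates 1, 2 and 3 gave 217, 171 and 92 and CTLA-4 KO replicates 1 and 3 gave 204 and 203. These fits have fewer arrays.

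With an estimated correlation 0 of 28 lists passed, and 14 did with the preset one (12 to 15 under the other alternatives). Of 308 results for lists that passed, 277 stayed past the threshold and 31 did not. Of 1108 for the named genes, 767 did and 341 did not. The median of anergy-associated genes turned from −0.062 to 0.026 under median centring, where the list no longer passed (adjusted p = 0.0673). Ctla4 kept a difference of −2.60 without moderation (adjusted p = 0.0538, elsewhere 1.33e-08 to 0.00124), and the odds ratio of its neighbours was 2.35 under median centring (Fisher's exact test, p = 0.0519) and 2.2 with the Actb term (Fisher's exact test, p = 0.123), with 2.4 to 4.47 elsewhere. Lists without moderation were not run, since camera moderates by itself. Dim probe sets limit all counts: the floor of 35.4 is near background.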

Other observations

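The genes described next, the tests of gene families, of neighbouring stretches and of cell markers, the counts of other splits and the Actb term were all chosen after the results were seen.

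Further genes that rose in CTLA-4 KO cells included Gadd45b, a stress-induced gene that acts upstream of p38, from 447 ± 78.1 to 1370 ± 130 (adjusted p = 0.00193), and Icam1, an adhesion ligand, from 752 ± 39.7 to 1510 ± 47.5 (0.00422). The kinase gene Pim1 rose from 495 ± 75.5 to 1100 ± 110 (0.00906), Crip1 from 3060 ± 419 to 6460 ± 800 (0.00537), and the transcription factor genes Irf8 from 1110 ± 262 to 2200 ± 106 (0.0193) and Ikzf3 from 1330 ± 339 to 2600 ± 289 (0.0297). Phgdh, the first enzyme of serine synthesis, rose from 4220 ± 315 to 6440 ± 475 (0.0193). Among those that fell were Itm2a, from 10200 ± 956 to 6470 ± 348 (0.0131), Ift80, from 2960 ± 154 to 1380 ± 146 (0.00223), the syntaxin gene Stx16, from 4860 ± 315 to 2680 ± 357 (0.00986), and the guanylate-binding protein genes Gbp6, from 2260 ± 238 to 1350 ± 81.7 (0.0173), and Gbp8, from 3080 ± 580 to 1520 ± 267 (0.0215). Pik3ip1, an inhibitor of PI3K, fell from 452 ± 17.6 to 211 ± 49 (0.0268).

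Several changed genes belonged to families, and the hypothesis that each family moves as a group was tested over 4 families. Of 24 measured S100, annexin and galectin genes 4 rose and none fell, namely Lgals3, S100a6 (2740 ± 872 to 6550 ± 676), Anxa2 (3950 ± 678 to 7900 ± 1410) and Lgals1 (13200 ± 1720 to 19100 ± 407), with a camera adjusted p of 0.00232 (adjusted p = 0.159 with an estimated correlation). For Ms4a genes, where Ms4a4c fell among 9, it was 0.0399, and for Slfn genes, where Slfn8 fell from 1520 ± 78.8 to 874 ± 85.1 among 7, it was 0.0472 (adjusted p = 0.159 with an estimated correlation for each). For 16 sialyltransferase genes, of which St8sia6 and St8sia4 (11000 ± 516 to 7460 ± 422) fell, it was 0.181. No family passed with an estimated correlation, so whether they move as groups was not decided.

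The 6 arrays can be split into 2 groups of 3 in 10 ways, which is too few for a share under 0.05. The real split gave 339 changed probe sets and the highest of the others gave 0, so 1 of 10 splits was as large. For gene lists the real split gave 14 and the others gave 2 to 7, so again 1 of 10 was as large. The preset camera test passed some lists under every split, so passing it does not by itself show a genotype difference. The other 3 splits that part all pairs gave 0 changed probe sets with and without the replicate block, where the real one gave 2341 with it.

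Genes near Ctla4 differed more often than other genes. Of 222 other stretches of 201 genes in a row, 0.901% (2 stretches) had as high a share of genes with an unadjusted p under 0.01 as the 20.8% around Ctla4, with a median of 6.56%, and the highest, 26.7%, also lay on chromosome 1. Without every member of the fixed lists the odds ratio was 3.24 (8 of 45, Fisher's exact test, p = 0.00648), which argues against list genes that lie there as the whole cause. With the Actb 5' to 3' ratio as a term the odds ratio was 2.2 and did not pass (Fisher's exact test, p = 0.123). DNA of the strain in which Ctla4 was targeted may therefore remain around the allele, and single differences there, such as those of Acadl and Bmpr2, could come from it or from the loss of CTLA-4, which these arrays do not separate. How far such DNA would reach is not known here, so the same stays open for Ap1s3, Lad1, Lancl1, Il1r1, Gpr25 and Dstyk on chromosome 1.

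Cd22, Cebpa, Dnase1l3 and Lgals3 rose in CTLA-4 KO cells though they are better known from B cells or myeloid cells. If B cells of the recipient had been sorted along, other B cell markers would have risen too, but the median of the other 7 was −0.23 (SD 0.31, highest 0.17), below the 1.97 that was lowest among the 4 genes. The median of 12 myeloid and dendritic cell markers was −0.175 (SD 0.42, highest 0.60). The abundant Cd74 had 199 ± 50 in wild type and 231 ± 25.5 in CTLA-4 KO, Cd79b 110 and 91.5, and Lyz2 57.8 and 30.2, while Ighm (9610 and 10700) and Ctss (13600 and 12200) were bright in both genotypes and could hide a small share. Transcription of the 4 genes by the T cells themselves may explain the pattern, as a hypothesis that was not tested further, and the gate of the sort is not given in the sources used here.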
